A study of Mus musculus with 6 samples.

How the data were processed

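The series measured chromatin accessibility by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in liver nuclei of male mice with 2 floxed genes. Of these, Ncor1 encodes the nuclear receptor corepressor NCOR1. Mice received an adeno-associated virus (AAV) carrying either eGFP (control, 3 libraries) or Cre recombinase (double knockout, dKO, 3 libraries). Livers were collected 5 days after the virus at zeitgeber time 10 (10 h after lights on). Nuclei positive for HNF4a, a hepatocyte transcription factor, were sorted before library preparation by Omni-ATAC, per the labels' protocols. The labels number the libraries 1 to 3 in each group and do not say that equal numbers mark paired animals or that each library came from its own animal, so p-values measure the spread between these libraries, which may in part be technical.

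The submitters' processing notes name Trim Galore 0.6.4, Picard, SAMtools 1.10 and HOMER 4.11 on the mouse build mm10. The aligner, the duplicate and mitochondrial filters, any shift of cut sites and the peak calling options are not given in the sources used here. Each library came with its own deposited peak list in the format of the HOMER peak finder, per the file headers, so peaks were not called on pooled replicates. The deposited lists give for each peak a normalized tag count, a signal that HOMER scales to library depth, a focus ratio (a fraction), a peak score, a fold over the local surroundings (a ratio), its p-value, and a clonal fold. The depth to which the authors scaled the signal was not given in the sources used here. The normalized tag count was the value analysed, and the score was used only to filter peaks within a list. The lowest peak score was 35.5 and the lowest fold over the local surroundings was 4 in each deposited list. A site inside a broadly open stretch can miss that local fold, so a site with no peak is not shown to be closed.

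The deposited peak width differed between lists. It was 108 bp in control 1, dKO 1 and dKO 2, 166 bp in control 2, and 172 bp in control 3 and dKO 3. Control 1 and control 3 each held 1 peak of another width. This width was treated as a technical batch with 2 classes, 108 bp against 166 or 172 bp. Both classes held libraries of both groups, so fold changes were also computed within each class. The 108 bp class held 1 control and 2 dKO libraries and the other class held 2 control and 1 dKO library. The smallest values in each file lay on a regular step, and 100% of the low values fell on it in every library. The step ranged from 0.04786 in control 2 to 0.06075 in dKO 3. If a step is 1 tag, the libraries differed in depth by up to 1.27 times, the lowest called values corresponded to 56 to 59 tags and the median peak to 209 to 251 tags. Whole counts could not be recovered for most larger values, which are rounded to few digits, so no count model was used.

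Peaks on chromosomes 1 to 19 and X were merged across libraries where they shared at least 1 bp. Peaks on chromosome Y, 17 to 24 per library, were left out. A region was called in a library that had a peak in it, and its value there was the highest normalized tag count of that library's peaks in the region. Regions called in all 6 libraries were compared as log2(value + 1), with each library centred on its median over these regions, by limma 3.58.1 with a mean-variance trend in R 4.3.3. The model had the group as its only term and 2-sided p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Fold changes are on the log2(value + 1) scale, dKO minus control, which understates the change of weak regions, and SE is the moderated standard error. Regions called in all libraries of one group and none of the other were counted. With 3 against 3 libraries an exact permutation test cannot give a p below 0.1.

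Gene symbols and spans came from a RefSeq gene table of the assembly GRCm38.p6, the same build as mm10. The table gives the start and end of each gene without strand, exons or transcription starts. The plan to link regions to transcription starts was therefore changed. Each region was linked to the nearest protein-coding gene span within 50 kb of its midpoint (distance 0 inside the span, ties by the nearer gene end), and regions within 1 kb of either end of a gene took the place of promoters. Whether a region lies in an exon, intron or UTR was not analysed here. No genome sequence was used, so the planned motif sets and any check of GC content were not run.

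The 15 gene lists and 7 marker lists of other liver cell types were fixed before the data were examined, as were the tests, the alternatives and the rule for named regions. In each of the gluconeogenesis, thyroid hormone receptor and clock lists, 1 name added no gene of its own, being another name of a listed gene or matching none, and all other names matched. Lists were tested by camera in limma with a preset correlation of 0.01, adjusted over all 22 lists together, and again with an estimated correlation. The named regions were all regions linked to the targeted genes, those linked to Pck1, G6pc, Tat, Fkbp5, Per1 and Ppargc1a, the 8 higher and 8 lower regions with the smallest p whose groups did not overlap (1 per gene; 1 higher and 1 lower region and 1 targeted gene are left out of the text), up to 3 genes per list with the smallest p of a linked region, and the 5 regions with the highest mean value called in each group alone.

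Alternatives covered the overlap needed to merge peaks, equal list lengths, the upper part of each list by score, the centring (none, quantile, cyclic loess), pseudocounts of 0 and 10, a minimum mean of 20, other ways to value a region, regions called in at least 3 libraries, blocks, limma settings, links within 10 kb and leaving out each library. The terms for peak width, the fits within a width class and the resized or joined peaks were added after the data were seen.

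The steps were tested on simulated data. Merging gave the right libraries and values for 2000 of 2000 simulated regions. With 200 of 51749 regions changed and variances drawn from the fitted distribution, limma found 75.5% of changes of 1 and 4.5% of changes of 0.5 on the log2 scale, and 5.10% of its calls were false. A first version of this simulation, which took the moderated variances as the true ones, gave 10.2% false calls. It was replaced after this was seen, since the moderated variances are shrunken estimates, and both values are given because the second version follows the assumptions of limma. With 10000 regions changed by 0.6 it found 75.7% (65.6% in regions of less than the median signal and 85.7% in the others), and 4.07% of calls were false. Among 220 camera tests of unchanged lists, 0 had an adjusted p under 0.05 and 5 had a p under 0.05, and a list shifted by -0.30 was called in 10 of 10 simulations. These simulated regions were independent of each other, which real regions are not. Merging used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.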

Results

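The data are ATAC-seq peak lists of sorted HNF4a-positive hepatocyte nuclei from 6 libraries, 3 of control livers and 3 of livers in which Cre was delivered to 2 floxed genes, Ncor1 and another (dKO). Per the series title, the study asks how corepressors that include NCOR1 act with the glucocorticoid receptor on hepatic gluconeogenesis. The comparison of dKO with control nuclei shows where accessibility differed 5 days after the virus. The control lists held 83371, 72417 and 68316 peaks and the dKO lists 84614, 81667 and 71473. The mean was 79251 ± 6896 in dKO and 74701 ± 7783 in control (SD, n = 3 each), a difference within the spread of libraries (exact permutation test, 2-sided, p = 0.5, smallest possible 0.1). Median normalized tag counts were 12.2 ± 1.3 in dKO and 12.4 ± 0.55 in control. The lists merged into 109853 regions, of which 51749 (47.1%) were called in all 6 libraries and 18282 (16.6%) in 1 library only.

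Of the targeted genes, Ncor1 is given here, with 6 regions called in all libraries. At Ncor1, a region at chromosome 11, 62352069 to 62352269 (mm10), rose from 24.8 ± 3.5 normalized tags in control to 34.0 ± 4.4 in dKO (SD, n = 3 each), a log2 fold change of 0.50 (SE 0.13, limma adjusted p = 0.0142). The other Ncor1 regions had log2 fold changes between -0.09 and 0.29 and were not called. Outside the shared regions, an Ncor1 region starting at 62449033 had a weak peak in all 3 dKO and no control libraries (5.97 ± 0.76 normalized tags), and one starting at 62409752 had a peak in all 3 controls (4.68, 7.9 and 7.57) and in dKO 3 (7.17) only. The sources used here do not say which exons are floxed, so these regions do not check the deletion. The Ncor1 call was lost without dKO 1 (adjusted p = 0.0641) or dKO 2 (0.0764), without centring (0.0977) and with regions called in at least 3 libraries (0.228).

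Across the genome, accessibility changed in both directions. Among the 51749 shared regions, 4240 (8.19%) were higher and 5995 (11.6%) lower in dKO, and 41514 were not called. The median log2 fold change was 0.67 for the higher regions and -0.58 for the lower ones, and 563 rose and 418 fell by more than 1. The called regions lay at 5299 of the 14710 genes with a shared region. The dKO values lay on one side of all control values in 3964 of the higher and 5132 of the lower regions. Over all shared regions this held for 28.4%, where chance gives 10%. With median centring, log2 fold changes fell as signal rose (Pearson r = -0.27 across regions), and the median was 24.1 normalized tags for lower regions and 12.7 for higher ones. Lower regions made up 58.6% of calls with median centring, 50.6% with quantile normalization and 64.5% without centring. The excess of lower regions thus depends on the scaling. Lower regions made up 49.9% of calls among regions with a mean of at least 20 and 47.3% in the upper part of the lists by score. Libraries were centred anew on those regions, so these shares do not tell the scaling from the regions used. In a model with a mean for each group and width class, which rests on 1 control library among the 108 bp libraries and 1 dKO library among the others, 4036 regions were higher and 7479 lower within the 108 bp libraries. Within the 166 or 172 bp libraries, limma called 0 regions, with 7516 at an unadjusted p under 0.05. As a test of a difference between the classes, limma called 0 regions, with 5393 at an unadjusted p under 0.05. Of all shared regions 72.5% had the same direction in both classes. Of the called regions 99.95% did, but they were selected on the same libraries, which favours such agreement. The counts fell to 1553 higher and 2151 lower without dKO 1, and to 1236 and 1410 without dKO 2.

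The first principal component of the shared regions held 61.5% of the variance and separated the groups. The dKO libraries scored 63.5, 53.6 and 12.7 on it, and the controls -45.2, -36.3 and -48.4, so dKO 3 lay nearest to the controls. The second held 16.0%, and control 1 had the highest score on it. Correlations of log2 values across regions, which are not independent replicates, were 0.95 to 0.96 between control libraries and 0.94 to 0.97 between dKO libraries. They were 0.93 to 0.95 between dKO 3 and the controls.

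**Figure D1:**
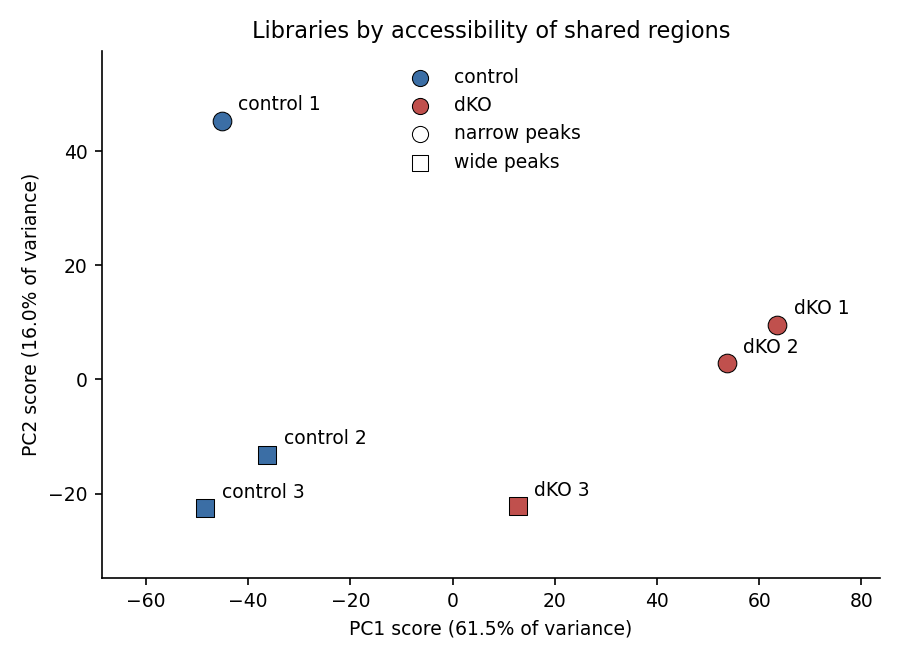
Scores of the 6 libraries on the first and second principal components of median-centred log2 values over 51749 shared regions, without units. Color gives the group and shape the deposited peak width; the controls lie below -36 on the first component and dKO 3, at 12.7, lies between them and the other dKO libraries.

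**Figure D2:**
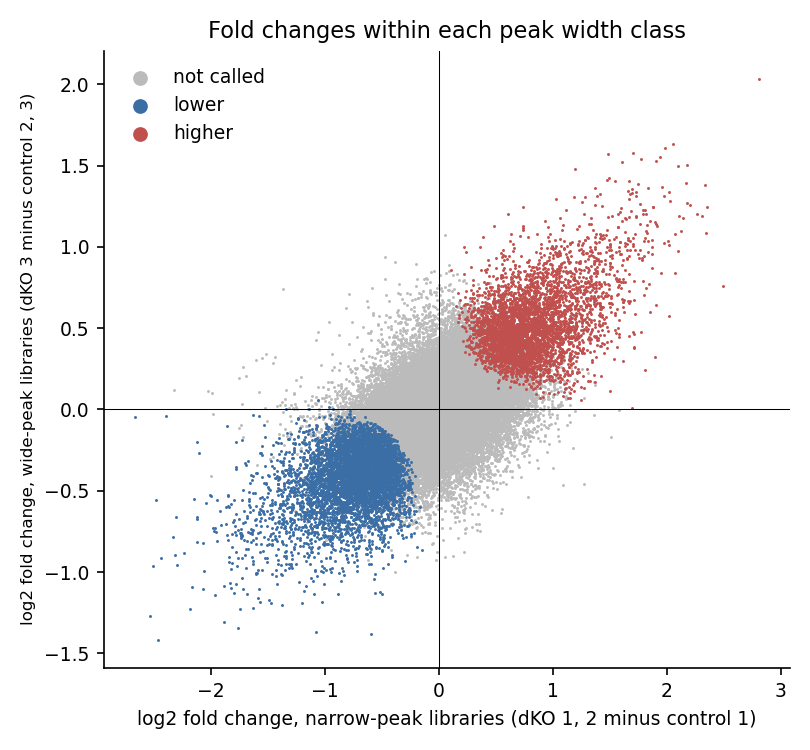
Log2 fold changes (dKO minus control) of each shared region in the 108 bp libraries (x axis) and in the 166 or 172 bp libraries (y axis), with color for the call over all 6 libraries. The fold changes of the 2 classes, which share no library, correlated across regions with a Pearson r of 0.69, and regions are not independent replicates.

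The regions with the smallest p among those that rose were led by a site inside the span of Msi2, an RNA-binding protein gene, at chromosome 11, 88639766 to 88639968. It went from 5.89 ± 1.04 normalized tags in control to 35.8 ± 5.6 in dKO (SD, n = 3 each), a log2 fold change of 2.48 (SE 0.18, limma adjusted p = 9.66e-05). It was 2.80 in the 108 bp libraries and 2.03 in the others. Inside Prdm2, a histone methyltransferase gene, a region at chromosome 4, 143118955 to 143119142, rose from 12.0 ± 0.98 to 35.9 ± 0.44. Near Fcgr3, which encodes an Fc receptor of immune cells, a region 8550 bp from the gene rose from 9.73 ± 0.63 to 35.7 ± 4.7, a log2 fold change of 1.83. A region inside Foxj2 (1.43), a forkhead factor gene, rose as well. So did regions 4999 bp from Txnip (1.48), 21519 bp from Zfp213 (1.95) and 5397 bp from Pom121l2 (1.71). Adjusted p for these 7 regions was at most 0.000403. Within the 108 bp libraries their log2 fold changes were 1.66 to 2.80, and within the 166 or 172 bp libraries 1.18 to 2.03.

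Among the regions that fell with the smallest p, a region inside Chn1, a Rac regulator gene, at chromosome 2, 73616557 to 73616932, went from 30.2 ± 2.4 to 8.89 ± 2.98 normalized tags (SD, n = 3 each), a log2 fold change of -1.63 (SE 0.16, limma adjusted p = 0.000403). Regions linked to the GTPase regulators Arhgap32 and Arhgap26 changed by -1.22 and -1.18. A region 5649 bp from Cps1, which encodes the enzyme that starts the urea cycle, at chromosome 1, 67116680 to 67116875, went from 33.5 ± 1.5 to 15.2 ± 2.2 (log2 fold change -1.04). Regions linked to Cyp2d10 (-1.48), a cytochrome P450 gene, Palld (-1.45), an actin-binding protein gene, and Rgs8 (-1.04), a G protein regulator gene, also fell. Adjusted p for these 7 regions was at most 0.000657. Their log2 fold changes were -1.09 to -1.78 in the 108 bp libraries and -0.84 to -1.34 in the others. Each of these 14 regions kept its call without each library and in every alternative over both width classes that tested it. They were picked for the smallest p and for groups that do not overlap in the same libraries, which favours keeping the call.

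**Figure D3:**
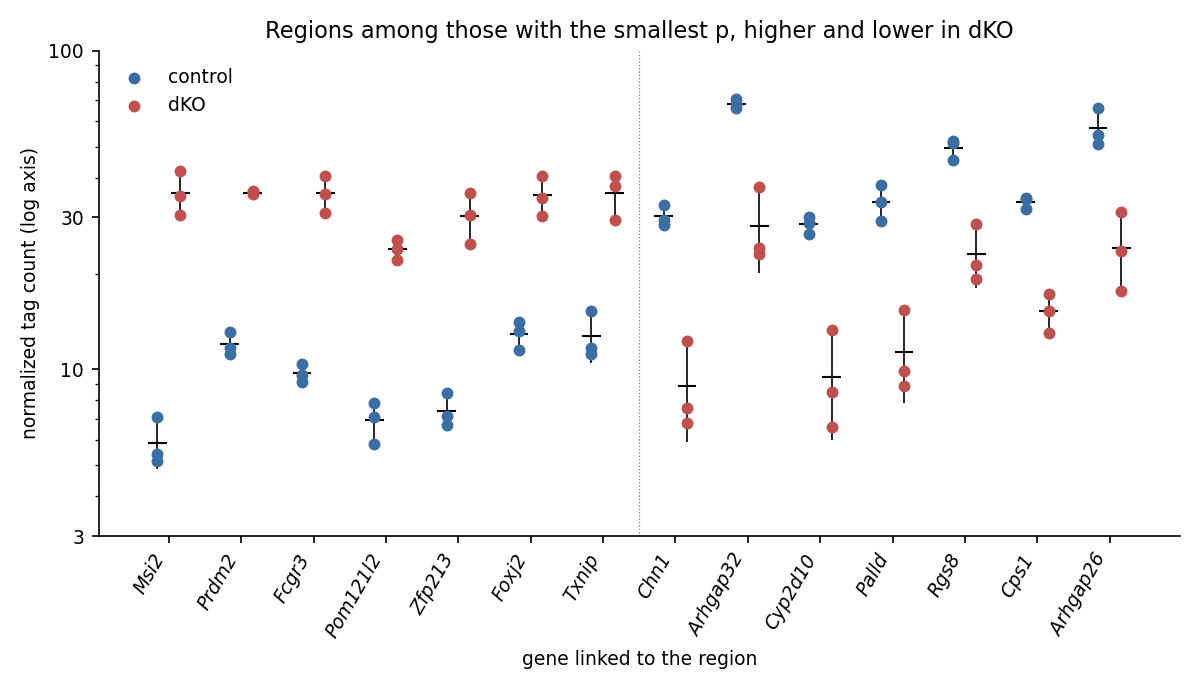
Normalized tag counts (log axis) of each library in 7 higher and 7 lower regions among those with the smallest p, named by linked gene, with lines for the mean and bars for 1 SD (n = 3 per group). By the rule that picked these regions, no dKO value overlaps the control values. The Msi2 region averages 5.89 in control and 35.8 in dKO, and the Chn1 region 30.2 and 8.89.

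Shared regions at Pck1, G6pc and Ppargc1a, the gluconeogenic genes named singly in advance, were lower in dKO or not called, and none was called higher. Outside the shared regions, a Ppargc1a region starting at 51551993 had a peak in all 3 dKO and no control libraries (8.76 ± 0.90 normalized tags). Ppargc1a, which encodes the coactivator PGC-1alpha, had 15 shared regions, of which 9 fell, by 0.44 to 0.98 on the log2 scale. At chromosome 5, 51868257 to 51868468, inside the gene, the value went from 43.9 ± 1.0 to 27.3 ± 5.1 normalized tags (SD, n = 3 each; log2 fold change -0.62, SE 0.11, limma adjusted p = 0.00343). It was -0.73 in the 108 bp libraries and -0.48 in the others. Of these 9 regions, that at 51553784 lost its call under quantile normalization (adjusted p = 0.0837), as did that at 51527909 (0.0594), and both under cyclic loess (0.0771 and 0.0598). The former also lost it without centring (0.0793) and with the peak width as a term (0.0698). Without dKO 1 or without dKO 2 the same 5 lost it, up to 0.208 and 0.181, and some of them also without control 1, control 2 or control 3, up to 0.111. With regions called in at least 3 libraries, only that at 51868257 kept its call (limma adjusted p = 0.0423). The others of the 9 then had adjusted p of 0.0511 to 0.122. Pck1, which encodes the cytosolic enzyme phosphoenolpyruvate carboxykinase, had 2 shared regions. The one at chromosome 2, 173146790 to 173146993, 6182 bp from the gene, went from 57.0 ± 3.7 to 37.3 ± 6.9 (log2 fold change -0.55, SE 0.11, adjusted p = 0.00594), and the other was -0.24 (adjusted p = 0.273, but 0.0265 without control 3). G6pc, the glucose-6-phosphatase gene, had 4. The one 5257 bp from the gene, at chromosome 11, 101362350 to 101362568, went from 31.8 ± 0.64 to 20.7 ± 6.9 (-0.58, SE 0.15, adjusted p = 0.0144), while one 1238 bp from it was 0.19 (adjusted p = 0.688). The G6pc call was lost without dKO 1 (adjusted p = 0.0841) or dKO 2 (0.0949). With regions called in at least 3 libraries, the Pck1 call (limma adjusted p = 0.0584) and the G6pc call (0.0917) were both lost.

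Among the glucocorticoid receptor targets named in advance, Tat, which encodes tyrosine aminotransferase, had 3 of 5 shared regions called lower. They changed by -0.59, -0.62 and -0.62, with adjusted p of 0.0170, 0.0125 and 0.00825. The last lies inside the gene at chromosome 8, 109986433 to 109986639, where values went from 41.3 ± 6.1 to 25.5 ± 4.5 normalized tags (SD, n = 3 each). Without dKO 1 their adjusted p was 0.0517 to 0.0755, so all 3 lost their call. Without dKO 2 it was 0.0460 to 0.112 and 2 lost their call, and the region at 109979494 also lost it without control 1 (0.0549) or control 2 (0.0630). With regions called in at least 3 libraries all 3 lost their call, with limma adjusted p of 0.055 to 0.089. Fkbp5, a co-chaperone gene of the receptor, had 8 shared regions and none was called, with log2 fold changes from -0.50 to 0.45. The Fkbp5 region 28 bp from a gene end was -0.41 (adjusted p = 0.0631), and the single shared region in Per1, a clock gene, was -0.40 (adjusted p = 0.0704). A region 578 bp from Per1 had a peak in all 3 dKO and no control libraries (21.6 ± 2.7 normalized tags). With the peak width as a term, added after the data were seen, both were called lower (adjusted p = 0.0319 and 0.0457), as they were without control 3 (0.0325 and 0.0313). Without control 3 a Tat region 387 bp from the gene (-0.66) was called too (0.0155), as was the Fkbp5 region 12371 bp from the gene (0.45, 0.0449), and without control 2 the Fkbp5 region at 28428976 (-0.50, 0.0229). Several strong peaks at these genes were called in some libraries only. A site 837 bp from Pck1 had 136.3 normalized tags in control 1, 84.5 in dKO 2 and 136.1 in dKO 3 and no peak in the others.

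By camera with the preset correlation, 5 gene lists were lower in dKO, and none of the 22 lists was called higher. None of these 5 calls held with an estimated correlation. Lists share genes, so their results are not independent. Of 25 receptor target genes 11, and of 24 amino acid genes 7, are also in another list. Tat is in the gluconeogenesis, receptor target and amino acid lists. Amino acid catabolism and urea cycle genes had 79 shared regions, of which 3 rose, 41 fell and 35 were not called (adjusted over the list alone, 3 and 46). The mean log2 fold change was -0.37 ± 0.42 (SD over regions; camera adjusted p = 2.37e-09, and adjusted p = 0.583 with an estimated correlation). Besides Cps1, a region 1175 bp from Cth, a cysteine synthesis gene, went from 54.5 ± 6.2 to 28.1 ± 2.7 (log2 fold change -0.87), and one 35716 bp from Glul, the glutamine synthetase gene, rose from 4.55 ± 0.19 to 10.2 ± 1.2 (1.07). Of 102 regions at hepatocyte identity genes, 3 rose and 32 fell (adjusted over the list alone, 7 and 41), with a mean of -0.29 ± 0.41 (adjusted p = 3.50e-06, and adjusted p = 0.583 with an estimated correlation). A region 13070 bp from Alb, the albumin gene, changed by -1.06 and one near Fgg, a fibrinogen gene, by -0.99. Of 77 regions at acute phase and inflammation genes, 1 rose and 26 fell (adjusted over the list alone, 4 and 31), with a mean of -0.29 ± 0.37 (adjusted p = 9.56e-06, and adjusted p = 0.583 with an estimated correlation). Regions at Saa1 (-1.01), a serum amyloid gene, and Il6ra (-0.90), the interleukin 6 receptor gene, fell, and one 895 bp from Hpx, the hemopexin gene, rose by 1.03.

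Gluconeogenesis genes had 96 regions, of which 10 rose and 29 fell (adjusted over the list alone, 11 and 32), with a mean of -0.16 ± 0.43 (camera adjusted p = 0.0281, and adjusted p = 0.683 with an estimated correlation). Single genes held many of these: 9 that fell were at Ppargc1a and 3 at Tat, and 6 that rose were at Slc16a1. Regions inside Foxo3 (-1.24), a forkhead factor gene, and 14026 bp from Gpt2 (-0.85), an aminotransferase gene, fell. A region 38360 bp from Irs2 (1.06), an insulin signalling gene, rose. Glucocorticoid receptor targets had 112 regions, of which 14 rose and 28 fell (adjusted over the list alone, 15 and 38), with a mean of -0.16 ± 0.45 (adjusted p = 0.0228, and adjusted p = 0.683 with an estimated correlation). Regions at Lpin1 (-0.86), a lipid metabolism gene, and Hsd11b1 (26.9 to 12.5 normalized tags), the gene of an enzyme that regenerates glucocorticoid, fell. One at Pdk4 (0.83), a pyruvate dehydrogenase kinase gene, rose. Of the 3 shared regions at Pdk4, 1 was called higher and 1 lower. The gluconeogenesis call was lost with quantile normalization (adjusted p = 0.141) and without control 1 (0.0662), control 2 (0.0834) or dKO 3 (0.0717), and that of receptor targets without control 1 (0.117). Mean log2 fold changes in the 108 bp libraries and in the others were -0.47 and -0.25 for amino acid catabolism, -0.36 and -0.17 for hepatocyte identity, -0.35 and -0.18 for acute phase, -0.21 and -0.11 for gluconeogenesis and -0.27 and -0.06 for receptor targets.

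The other 10 gene lists were not called, though each held called regions. At PPAR alpha targets, 15 of 75 regions rose and 9 fell (adjusted over the list alone, 17 and 10; mean 0.09 ± 0.44, camera adjusted p = 0.103). Regions at Acot1 (1.11), an acyl-CoA thioesterase gene, Pdk4 (0.83) and Pex11a (0.73), a peroxisome gene, rose. This list was called higher with quantile normalization (adjusted p = 0.00654), with links within 10 kb (0.0237) and without control 1 (0.0311), each at the preset correlation; over all 6 libraries it had adjusted p = 0.683 with an estimated correlation. At sterol synthesis genes 1 of 68 regions rose and 17 fell (list alone, 1 and 18; mean -0.13, adjusted p = 0.0845). Regions at Stard4 (-0.92), Hsd17b7 (-0.65) and Dhcr7 (-0.69), genes of sterol transport and synthesis, fell, though the Hsd17b7 call was lost when the peaks of a region were summed (adjusted p = 0.211). This list was called lower with links within 10 kb (adjusted p = 0.00632), with the peak width as a term (0.0204), and without control 3 (0.0133) or dKO 1 (0.0346), each at the preset correlation; over all 6 libraries it had adjusted p = 0.766 with an estimated correlation. Lipogenesis and triglyceride synthesis genes had 18 regions that rose and 21 that fell of 130 (list alone, 24 and 26; adjusted p = 0.841), with higher regions at Plin2 (1.56), a lipid droplet gene, and Me1 (1.56), the malic enzyme gene, and a lower one in Lpin1 (-0.86).

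Bile acid genes had 7 regions that rose and 16 that fell of 79 (adjusted over the list alone, 12 and 20; camera adjusted p = 0.183), with higher regions inside Abcb11 (1.16) and Abcb4 (1.18), genes of canalicular transporters, and a lower one linked to Slco1b2 (-0.95), an uptake transporter gene. LXR targets had 8 higher and 4 lower of 48 (list alone, 8 and 4; adjusted p = 0.880), with rises at Lpl (0.46), Abcg5 (0.68) and Scd1 (0.47). Without dKO 2 the adjusted p was 0.0593 for Lpl, 0.0615 for Abcg5 and 0.113 for Scd1, without dKO 1 it was 0.0717 for Abcg5 and 0.0712 for Scd1, and without control 3 it was 0.0755 for Scd1. Without centring the Lpl and Scd1 calls were lost too (0.120 and 0.115). Thyroid hormone receptor targets had 14 higher and 18 lower of 89 (list alone, 21 and 22; adjusted p = 0.841), with rises at Thrb (1.03), the receptor gene, Serpina7 (1.09) and Me1 (1.56). Circadian clock genes had 19 higher and 18 lower of 125 (list alone, 24 and 25; adjusted p = 0.880). Regions linked to the clock factors Nfil3 (1.16) and Arntl (1.24) rose and one in Rora (-1.39) fell. Of the 33 shared regions at Rora, however, 6 were called higher and 3 lower. Xenobiotic metabolism genes had 7 higher and 10 lower of 78 (list alone, 7 and 10; adjusted p = 0.580), with Ugt2b1 (-0.95) and Por (-0.67) lower and Aldh1a1 (0.93) higher. Cell cycle and p53 genes had 4 higher and 8 lower of 63 (list alone, 4 and 8; adjusted p = 0.880), with Trp53inp1 (-0.63) and Mcm5 (-0.75) lower and Gadd45b (0.70) higher. Fetal liver and stress genes had 7 higher and 5 lower of 47 (list alone, 8 and 5; adjusted p = 0.580). A region 49391 bp from Dlk1 (-1.77) and regions linked to the fetal genes Afp (-0.86) and Igf2 (-0.68) fell. Afp also had a higher region, with 1 higher and 1 lower of 3. The stress genes Atf3 and Trib3 each had 2 higher regions and 0 lower. The calls at Por, Mcm5, Gadd45b and Igf2 were lost without dKO 2 (adjusted p = 0.0536, 0.0544, 0.0658 and 0.0817), and that at Mcm5 without dKO 1 (0.0515). Mean, median and test did not share a sign for the LXR, thyroid, clock and cell cycle lists.

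Markers of other liver cell types were not called as lists. Cholangiocyte markers had 4 of 28 regions higher and 0 lower (adjusted over the list alone, 4 and 0; mean log2 fold change 0.15 ± 0.36, camera adjusted p = 0.123), and were called higher without control 3 at the preset correlation (adjusted p = 0.0397); over all 6 libraries they had adjusted p = 0.683 with an estimated correlation. Stellate cell and fibroblast markers had 2 of 17 higher (list alone, 2; mean 0.12 ± 0.27, adjusted p = 0.248). Sinusoidal endothelial markers had 2 higher and 6 lower of 38 (list alone, 2 and 6; mean -0.13 ± 0.42, adjusted p = 0.592). Macrophage markers had 6 shared regions, at 2 genes, with 1 higher and 1 lower (list alone, 1 and 1; adjusted p = 0.880). Lymphocyte markers had 6, neutrophil markers 5 and red cell precursor markers 5, with 0 called in limma (list alone, 0; adjusted p = 0.592, 0.841 and 0.880).

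**Figure D4:**
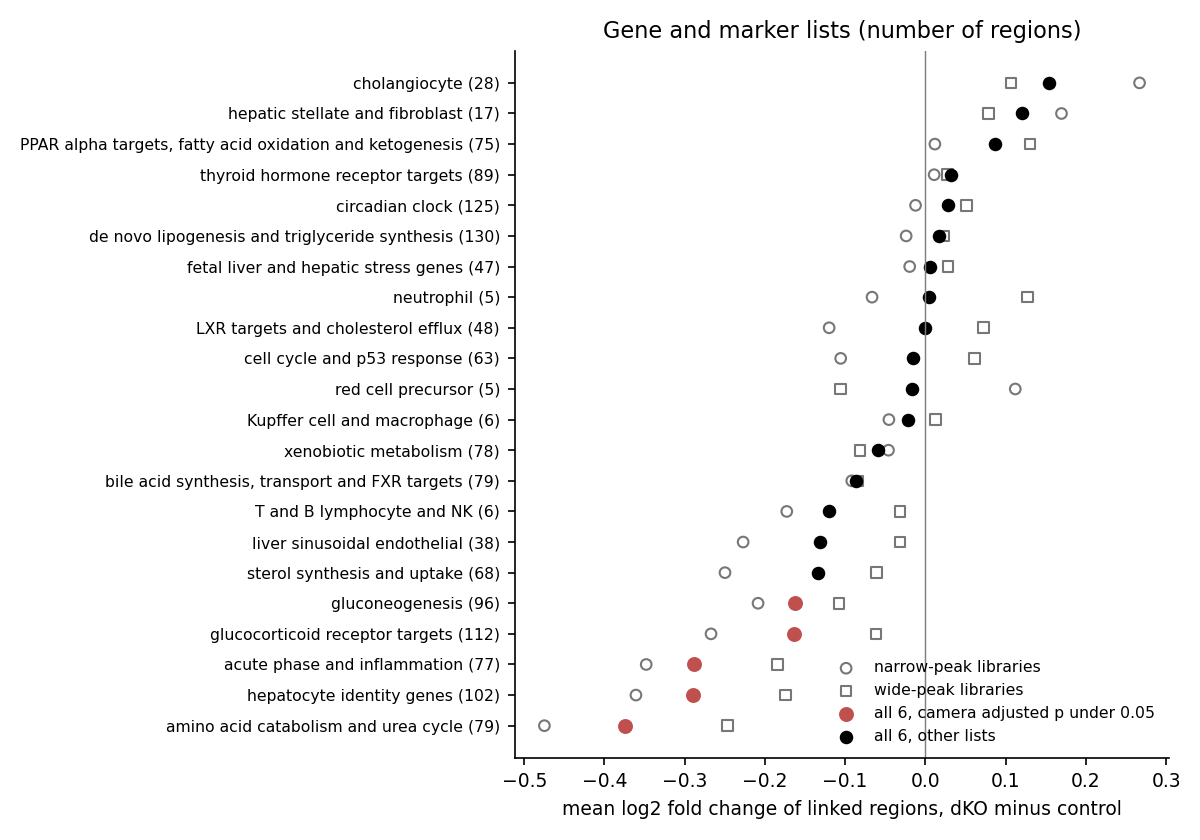
Mean log2 fold change (dKO minus control) of the regions linked to each list, with the number of regions in brackets, over all 6 libraries (filled) and within each peak width class (open). The lists called by camera with the preset correlation lie between -0.37 and -0.16; none was called with an estimated correlation.

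Regions within 1 kb of a gene end were slightly lower against the rest with the preset correlation and median centring, but not with an estimated correlation or quantile normalization. Of 11487 such regions 317 were higher and 1208 lower, and they made up 7.48% of higher regions, 20.2% of lower regions and 22.2% of all shared regions (Fisher exact test, higher against lower, 2-sided, odds ratio 0.32, p = 1.91e-75, which treats regions as independent). The mean log2 fold change was -0.09 near gene ends and 0.00 elsewhere (camera, p = 0.00103, where an exact permutation over the 10 splits of the libraries gave a p as low in 4 of them). The p was 0.486 with an estimated correlation and 0.934 with quantile normalization, where the means were -0.01 and 0.00.

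Some regions had a peak in one group alone. Peaks in all 3 dKO and no control libraries made 1723 regions, and the reverse made 1468. The dKO-only regions with the highest means were at Gstm3 (108.2 ± 24.5 normalized tags in dKO, SD, n = 3), Gstm1 (104.1 ± 16.3), both glutathione transferase genes, Abcc2 (97.6 ± 29.6), a bile canalicular transporter gene, G0s2 (84.3 ± 11.1), a lipolysis inhibitor gene, and Pdk4 (77.4 ± 5.8). The control-only ones were at Trf (72.2 ± 6.3), the transferrin gene, Agpat2 (64.8 ± 1.0), a lipid synthesis gene, Pim3 (63.8 ± 2.0), Tsku (59.4 ± 5.9) and Pcdh1 (58.8 ± 4.0). Gstm3, Abcc2 and Pdk4 also had control-only regions (the strongest at 22.2 ± 1.2, 37.1 ± 3.0 and 42.7 ± 7.1), and Pcdh1 had a dKO-only one (5.14 ± 1.92), so these genes had regions exclusive to each group. The nearest region called in the other group lay 249 bp (Abcc2) to 5982 bp (Gstm1) from these sites, with up to 74.2 normalized tags there. Most group-only regions were weaker, with a median of 6.90 tags in dKO-only and 5.61 in control-only regions. Within 1 kb of a gene end lay 163 (9.46%) of the dKO-only and 96 (6.54%) of the control-only regions (Fisher exact test, 2-sided, odds ratio 1.49, p = 0.00274). This p treats regions as independent, which they are not, and does not measure the spread between libraries. No list was found to differ between the classes (Fisher exact test, adjusted p = 1 for each of 22 lists), but counts were small. The PPAR alpha list held the most, 11 dKO-only and 12 control-only regions. The macrophage, cholangiocyte and red cell precursor lists held 0 in both, where the outcome was fixed. Such counts could show only large differences, so the lists are not shown to be alike. Splitting the 6 libraries by peak width gave 5807 regions exclusive to one side, against 3191 for the groups and at most 482 for the other 8 splits. Counts rose to 6438 dKO-only and 3212 control-only without dKO 3, and to 3787 and 2498 without control 1. Control-only regions rose to 2407 without control 2 and 2304 without control 3.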

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

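The terms and fits for peak width, the gene end tests with quantile normalization or the width term, the resized and joined peaks and the list tests without centring were chosen after the data were seen. Of 10235 called regions, 9080 (88.7%) kept call and direction with peak width as a term, 7576 with quantile normalization, 7515 (73.4%) with cyclic loess and 6998 (68.4%) without centring, but only 3574 (34.9%) without dKO 1, 2582 (25.2%) without dKO 2 and 1146 (11.2%) with regions called in at least 3 libraries, and in none of the alternatives that tested the same regions was a call reversed. Counts of higher and lower regions moved by over 1.5 times in the following cases, whose cause was not tested. They were 2488 and 2232 in the upper part of the lists by score and 1963 and 1953 with a mean of at least 20. Fewer regions entered in these 2 cases, but libraries were also centred anew on them. Of 4783 called regions tested again in the upper part, 3264 (68.2%) kept the call. With a mean of at least 20, 2830 of 4571 (61.9%) did. With regions called in at least 3 libraries, which fills uncalled values, counts were 1591 and 1531. With array weights they were 9080 and 11533, and without centring 2562 were higher. Counts within the 166 or 172 bp libraries, where 1 dKO library stands alone, moved too. Leaving out single libraries gave 1236 to 5262 higher and 1410 to 8273 lower regions, lowest without dKO 2 and highest without dKO 3; without dKO 1 they were 1553 and 2151. The same gave 1960 to 6438 dKO-only regions (1723 with all libraries) and 1685 to 3212 control-only regions (1468), since fewer libraries need to share a call; the highest of both were without dKO 3. The difference in peak number, 4550, ranged from 1357 without control 3 to 8885 without control 1, and was 1869 without dKO 1 and 8439 without dKO 3. The number of lists called fell from 5 to 0 with an estimated correlation, and 1 marker list (cholangiocyte, adjusted p = 0.683 with an estimated correlation) was called without control 3. The difference of regions near gene ends, -0.10 (camera in limma, p = 0.486 with an estimated correlation), was -0.009 (p = 0.934) with quantile normalization. Whether equal replicate numbers mark paired libraries stays open. Deviations of equal numbers correlated at 0.15, -0.03 and 0.23. Of the controls, dKO 1 correlated best with control 1, dKO 3 with control 3, but dKO 2 with control 1. Each of these best matches shared a peak width class, so the correlations cannot tell pairing from width. A replicate block gave 5417 higher and 7384 lower regions and the same 5 lists. The block also called 3 Fkbp5 regions (adjusted p = 0.0339 to 0.0378), the Per1 region (0.0437) and the Tat region 387 bp from the gene (0.0142), which the same model without the block did not call. Of 74 named regions called, 35 lost the call with regions called in at least 3 libraries (among them regions at Abcb11, Abcb4, Abcg5, Afp, Aldh1a1, Dhcr7, G6pc, Gadd45b, Glul, Hpx, Igf2, Il6ra, Lpl, Mcm5, Ncor1, Pck1, Pex11a, Por, Ppargc1a, Scd1, Tat, Trp53inp1 and Ugt2b1), 18 without dKO 2, 14 without dKO 1, 5 without control 1 or without centring, and at most 4 under each other alternative over both width classes. The motif sets and their 100 bp window were not run. Depth was not varied; of simulated log2 changes of 0.6 in 10000 regions, 65.6% were found in regions of less than the median signal and 85.7% in the others, so fewer changes are found in weak regions.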

Other observations

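The tests of peak width, cyclic loess and marker lists, the split counts of regions and lists, the use of the spread of marker regions, which moved that test from excluded to open, the intervals of the nuclei share and of the distance between peaks, the test of that distance, and the choice of the genes in the next paragraph came after the values were seen.

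Many genes carried several regions that moved together. Pde4d, a cyclic AMP phosphodiesterase gene, had 43 shared regions, of which 16 were higher and 1 lower. Msi2 had 10 of 19 higher and 0 lower, Sgms1, a sphingomyelin synthase gene, 9 of 19, Lipc, the hepatic lipase gene, 8 of 15, and Map3k13 8 of 10. In the other direction, Cmah had 9 of 11 regions lower, Car1, a carbonic anhydrase gene, 8 of 12, Klf15, a regulator of gluconeogenic and amino acid genes, 7 of 8, Irf2 7 of 13 and Alb 6 of 7, each with 0 higher. Of 2894 genes with 5 or more shared regions, 39 had at least 5 higher and 0 lower, 47 had at least 5 lower and 0 higher, and 111 had at least 5 called regions that went both ways. Among 2640 neighbouring pairs of called regions within 20 kb, 83.6% shared a direction, against a mean of 51.5% and a highest value of 54.6% in 1000 permutations of the directions, so called neighbours did not change independently.

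The group difference itself was weighed first. Only 10 splits of the 6 libraries exist, too few for a share under 0.05; 1 of them, the real one, gave 10235 regions, and the highest other gave 0. Width does not account for most calls, since 88.72% kept call and direction with it in the model. A trend with signal strength does not account for most calls either, since 73.42% did so under cyclic loess. It may bear on the calls that were lost there. The share required was set after the values were seen and was lower for cyclic loess than for width. More nuclei of other liver cell types in dKO stay open, although nuclei were sorted on HNF4a. The median log2 fold change was -0.0926 (95% bootstrap interval over regions, taken as independent, -0.23 to 0.05) for sinusoidal endothelial markers, whose members went both ways with an SD of 0.42, 0.12 (0.02 to 0.28) for cholangiocyte and 0.13 (0.02 to 0.20) for stellate markers.

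For the lists and gene ends the splits say less. At least as many lists as in the real split, 5, were called in 6 of the 10 splits, the real one among them. The highest number, 7, came from a split that mixes the groups. A camera p as low as the real 0.0010 near gene ends came from 4 of the 10 splits, the real one among them, down to 2.0e-11. With so few splits no share under 0.05 is possible. Splits that mix the groups call lists as often. Each of them has unequal numbers of dKO libraries on its sides, so part of the group difference stays in it. Whether correlation among the regions of a list gives these calls was not tested.

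The dKO 3 library was placed on an axis from the control mean (0) to the dKO mean (1) of the other libraries, using regions called without it. It stood at 0.54, against 1.23 for left-out dKO 1 and 1.08 for left-out dKO 2, a shortfall of 0.6199 from their mean. The dKO mean used to place dKO 1 or dKO 2 included dKO 3, which raises their positions, so this shortfall is overstated. On its own axis dKO 3 still fell short of 1, the mean of dKO 1 and dKO 2. Each left-out dKO library was placed by the same steps and only dKO 3 fell short of 1, so selection of regions alone does not account for the position of dKO 3. Its peak width does not either, since control 1, with the width of dKO 1 and 2, stood -0.0552 from the mean of controls 2 and 3 rather than toward dKO. A share of control-like nuclei in dKO 3, such as cells without recombination, may contribute: the median share implied was 0.52 in regions that rose and 0.42 in those that fell, a difference of 0.0978 (95% bootstrap interval 0.087 to 0.11) around the bound of 0.1 set for a common share. The difference alone met that bound, and the interval, added once it was seen, leaves this open.

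Regions called in all 108 bp libraries and no other numbered 5093. Weak peaks do not account for them, since their median value of 12.4 normalized tags was 3.938 times the mean of the lowest called values. A minimum distance between peaks that grows with peak width may contribute. Of these regions 19.281% (95% exact binomial interval 18.2 to 20.4, around the bound of 20% set for excluding it) had the midpoint of a region of all 3 wider lists within 344 bp, against 0.232% of dKO-only regions. The median distance was 548.5 bp against 6554 bp. Each dKO-only region already holds a dKO 3 peak, from which such a minimum distance would keep other dKO 3 peaks. The dKO-only regions therefore give no background rate. A merged region lay within 200 bp of 30.3% of the regions called in the 108 bp libraries only, against 7.65% of regions called in all libraries. The distance used to call the peaks is not given in the sources used here, so this stays open.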
